A study of Mus musculus with 9 samples.

How the data were processed

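RNA was taken from whole pancreas that had been snap-frozen and ground, per the labels' protocols, from 8-week-old mice with 3 animals per group. PolyA RNA was made into strand-specific libraries (NEBNext Ultra II Directional) and sequenced as paired-end reads of 150 bp, with about 40 M read pairs per sample stated in the labels. Per the submitters' processing notes the tools included DESeq2 and the genome builds named were GRCm38 and mm10. The aligner, the counter and the annotation release were not given in the sources used here. Ground tissue holds every cell type of the organ and any tissue dissected with it, and counts of near-identical genes depend on how the authors assigned reads that match several places.

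The authors deposited 1 table of 46078 genes by 9 libraries, in which each value is a normalized count, that is, a signal made by dividing gene counts by 1 size factor per library. In each library every value was a whole multiple of the smallest value: 100% of values lay within 1e-06 of a whole number of reads. Dividing by that step gave back whole reads, 13461427 to 21034501 per library. For S6k2_RK replicate 1 the step was 1.00, so close to 1 that a general test of the steps cannot tell it from rounding; tests on reads were therefore run with all 9 libraries and again without it. The value of 1 read ranged from 0.774 to 1.34 normalized counts. Libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom from 8.16 to 22.2), so none was a copy of another. The 3 animals per group and this depth set the precision: in simulated data with the same genes, limma recovered 75 of 100 changes of 2-fold and 14 of 100 changes of 1.41-fold for Snd1_KI against WT, and 70 and 4 of 100 for S6k2_RK against WT. The changed genes left out those with the lowest means and were far fewer than the genes called against WT in the data. These rates are therefore only a guide. Intervals and floors cover counting error only.

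Gene symbols were taken from the table, and 3737 of 4669 identifiers without one were named from a reference table. Coordinates are those of GENCODE mouse release 21 on GRCm38, which also gave transcript length and GC content for 99.9% of tested genes. Genes with a mean of at least 10 normalized counts over the 9 libraries were tested, 11953 in all. The test was limma 3.58.1 in R 4.3.3 on log2 of the normalized count plus 1, with a mean-variance trend and all 9 libraries in 1 fit, so that the groups share 1 estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Fold changes on this scale understate the change of genes with low counts. The comparisons were each mutant with WT, the mutants with each other, and the mean of both mutants with WT.

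There were 38 gene lists (pathways and markers of cell types) and a rule for the genes named, both set before the data were examined; 35 lists had at least 5 tested members. Lists were tested with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, adjusted over the lists of 1 comparison. On simulated lists of 20 genes camera called 100 of 100 shifted by 0.3 on the log2 scale and 4 of 100 unshifted ones, at an unadjusted p below 0.05. These genes were drawn independently, so the rates do not hold for lists whose members move together or for smaller shifts. The named genes include the targeted genes and their paralogue. For each mutant against WT they include the 10 rises and 10 falls with the largest log2 change among called genes whose libraries do not overlap and whose mean is at least 50. Symbols of the form Gm plus digits, ending in Rik or holding -ps, and genes without a symbol were left out, some of them protein-coding. Up to 4 members with the smallest p of each list past the threshold in either mutant against WT were added, and 5 rises and 5 falls for the other comparisons. Of the genes this rule names, 2 are not reported here. The choice of lists whose members are named was narrowed to those past the threshold in either mutant against WT after the alternatives had been computed. It left out members of other lists, 12 of whose values changed direction under an alternative, in lists that did not pass the threshold. Lists that passed only between the mutants are described in that comparison, and some members of lists that did not pass under other observations.

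Alternatives were other pseudocounts, count filters, scalings (equal totals, TMM, genes outside the enzyme and mitochondrial lists), a robust fit, array weights, only the groups compared, a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, and leaving out each library. A lymphocyte covariate, a correction for transcript length and GC, leaving out each pair of WT libraries, and the tests without S6k2_RK replicate 1 were added after the data were seen. Shares of counts were compared by exact permutation tests. Correlations between the mutants were set against 100 simulated draws in which all 9 libraries were unchanged. In each draw the simulated WT group served both comparisons, and genes were drawn independently. Figures were drawn with matplotlib 3.10.9. No column of values was left unused.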

Results

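Whole pancreas was profiled by polyA-selected, strand-specific RNA sequencing in 9 mice aged 8 weeks. There were 3 wild-type littermates (WT), 3 mice with a knock-in at Snd1 (Snd1_KI) and 3 mice with an S6k2 mutant allele labelled RK (S6k2_RK). Snd1 encodes a Tudor-domain protein that binds methylated arginine, and Rps6kb2 encodes S6K2, a kinase of the mTOR pathway. The base changes carried by the 2 mutants were not given in the sources used here. Each library held between 13461427 and 21034501 reads assigned to genes, and the number of genes detected was 16885 ± 204 in WT, 16271 ± 238 in Snd1_KI and 15556 ± 339 in S6k2_RK (mean ± SD, n = 3 each), without overlap between the groups (exact two-sided permutation p = 0.1 for each pair). Digestive enzymes and other secreted zymogen-granule proteins took 71.3% ± 0.843 of the counts in WT, 74.9% ± 0.494 in Snd1_KI and 76.4% ± 0.895 in S6k2_RK (mean ± SD, n = 3 each). The libraries of the groups did not overlap in this share, which rose as the number of genes detected fell, and the exact two-sided permutation p was 0.1 for each pair of groups, which is the smallest that 3 against 3 can give. Mitochondrially encoded transcripts took 1.27% ± 0.221, 0.818% ± 0.0689 and 0.783% ± 0.236 of the counts (exact p = 0.1 for Snd1_KI and 0.2 for S6k2_RK against WT, and 0.8 between the mutants). With near-identical enzyme copies left out, the enzyme share of both mutants still lay above WT, by 2.93 and 3.44 percentage points (exact p = 0.1 each). The enzyme share of S6k2_RK then exceeded that of Snd1_KI by only 0.504 points, with libraries that overlapped (exact p = 0.5).

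The targeted genes were measured first. Snd1 (ENSMUSG00000001424, chromosome 6, 28475139 to 28935162, GRCm38) stood at 1993 ± 162 normalized counts in WT, 2903 ± 244 in Snd1_KI and 2801 ± 433 in S6k2_RK (mean ± SD, n = 3). It rose in Snd1_KI by a log2 fold change of 0.54 ± 0.12 (SE, limma adjusted p = 0.0101) and in S6k2_RK by 0.48 ± 0.12 (adjusted p = 0.0115). The Snd1_KI call was lost without WT replicate 2 or Snd1_KI replicate 2 (highest adjusted p = 0.0699), and the S6k2_RK call without WT replicate 1 or S6k2_RK replicate 2 or 3 (highest adjusted p = 0.0546). Rps6kb2 (chromosome 19, 4153991 to 4163354) had 57.9 ± 6.83 normalized counts in WT, 43.8 ± 8.24 in Snd1_KI and 35.4 ± 17.8 in S6k2_RK. Neither difference passed the threshold (adjusted p = 0.459 and 0.0772), although S6k2_RK against WT did without S6k2_RK replicate 1 (log2 fold change -1.17, adjusted p = 0.00559). Its paralogue Rps6kb1 (chromosome 11, 86498871 to 86544805) had 453 ± 42.9, 397 ± 30.5 and 388 ± 12.6 normalized counts, with adjusted p = 0.38 and 0.228. A changed codon need not alter a transcript level, so these values do not check the labels.

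**Figure D1:**
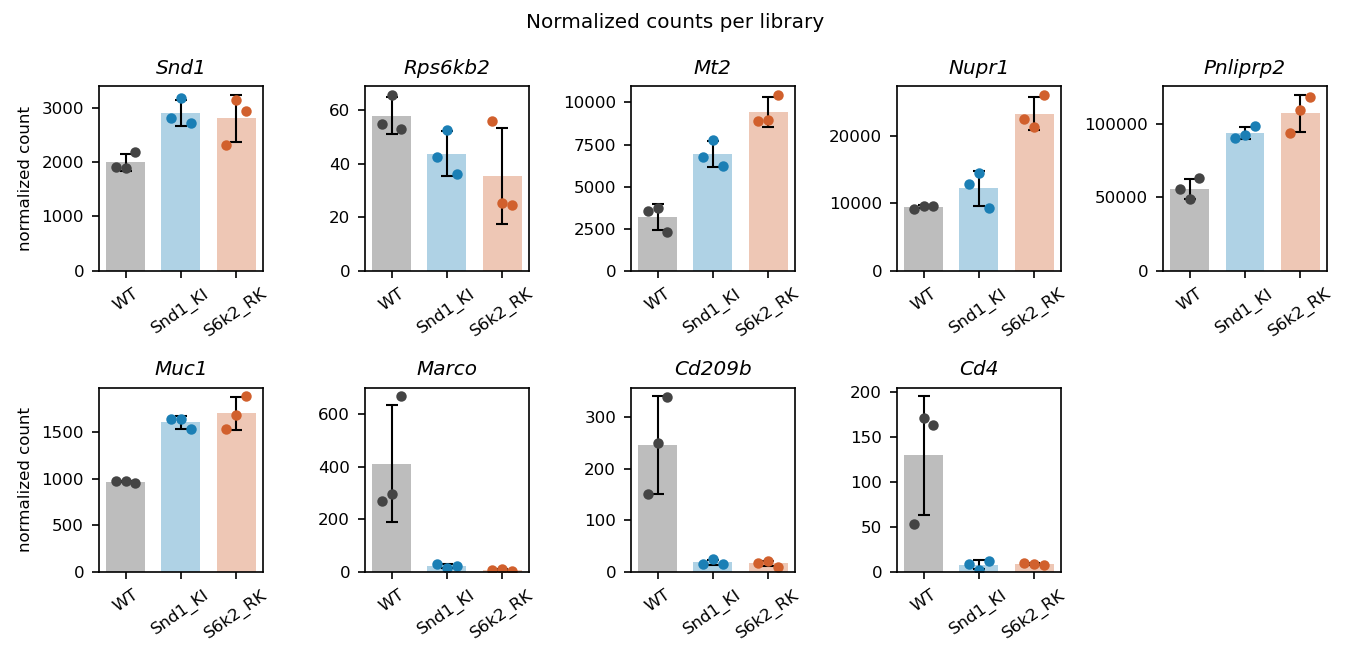
Normalized counts of 9 named genes in each of the 9 libraries, with the gene in the panel title and the group on the x axis. Points are libraries, bars are group means and error bars are 1 SD (n = 3). Marco, Cd209b and Cd4 lie far lower in every mutant library than in every WT library, and Mt2, Pnliprp2 and Muc1 lie higher.

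All log2 fold changes below are relative to the authors' scaling, under which the median gene did not move (0.0027 in Snd1_KI and 0.0024 in S6k2_RK). With every library set to the same total instead, the median gene shifted by -0.28 in Snd1_KI, by -0.51 in S6k2_RK, by -0.24 between the mutants and by -0.39 for their mean, so that a higher value means higher than the median gene. Under that scaling 11 of the 37 named rises of S6k2_RK against WT changed sign, Snd1 among them (-0.04), and none of the 30 named rises of Snd1_KI against WT did.

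The Snd1 knock-in was compared with WT to ask how the mutation changes the pancreatic transcriptome. In Snd1_KI 14 of 16 T-cell markers and 11 of 13 B-cell and plasma-cell markers were lower, while single genes such as the metallothionein Mt2, 4 of 35 digestive enzymes and 4 of 11 acinar regulators were higher under the authors' scaling (1 of the 11 was lower). Marco, a scavenger receptor of marginal-zone and sinus macrophages, fell from 411 ± 221 to 23.1 ± 7.42 normalized counts (log2 fold change -4.02 ± 0.35 SE, limma adjusted p = 5.5e-06). Cd209b, a lectin of the same macrophages, fell from 245 ± 93.7 to 19.1 ± 5.63 (-3.58 ± 0.31, adjusted p = 5.5e-06). Glycam1, a mucin of high endothelial venules, fell from 169 ± 90.5 to 1.44 ± 2.50, and Ighg1, an immunoglobulin heavy chain that shares sequence with related genes, from 308 ± 178 to 7.98 ± 8.34. Among the rises, the metallothionein Mt2 went from 3205 ± 776 to 6924 ± 775 (1.14 ± 0.15, adjusted p = 0.000375). The linker histone H1f2 went from 188 ± 43.4 to 448 ± 121, and the fatty acid desaturase Fads2 from 125 ± 14.2 to 258 ± 44.1.

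Of 11953 genes tested, 287 were higher and 383 lower in Snd1_KI (limma, adjusted p below 0.05). The balance turned with the settings: 45 were higher and 1581 lower with every library at the same total, and 243 higher and 166 lower among the 8097 genes with a mean of at least 50. Of the lower genes 253 differed by more than 2-fold, against 19 of the higher ones. In all, 3237 genes (27.1%) had groups that did not overlap, where chance gives 10%. Genes are named by size of change among called genes with a mean of at least 50 normalized counts and groups that do not overlap. Other falls among the 10 with the largest log2 change by this rule were those of Ltb, Ighd, Rac2, Igha and Ikzf1, genes of lymphocytes or other blood cells, with log2 fold changes from -2.72 to -2.43. The largest rise by this rule was that of the amylase copy Amy2a4, with 1218 reads in the 3 Snd1_KI libraries against 1 read in the 3 WT libraries. That ratio was 1179 after scaling (95% interval 211 to 46606, counting error only), and reads of the near-identical Amy2a copies may be divided unevenly. Amy2a5, another copy, had 11049 ± 5812 and 42718 ± 25114 normalized counts (1.91 ± 0.37, adjusted p = 0.00477). The kallikrein-family gene Klk1b11 (1.07 ± 0.15), BC034090 (1.17 ± 0.15) and Fam81a (1.05 ± 0.20) also rose. Lrrn4 (1.20 ± 0.29) and Zfp750 (1.11 ± 0.32) rose too. The Lrrn4 call was lost without WT replicate 2 or Snd1_KI replicate 2 or 3 (highest adjusted p = 0.14), and the Zfp750 call without WT replicate 1 or 2 or any Snd1_KI library (highest adjusted p = 0.231).

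Of the 35 fixed gene lists tested, 14 passed the threshold for Snd1_KI against WT (camera with a preset correlation of 0.01). The counts of rises and falls below are over all genes tested. T-cell markers had the lowest median, -3.37: 14 of 16 fell and none rose, with 16 falls adjusted over the list alone (camera adjusted p = 1.33e-18; adjusted p = 0.232 with an estimated correlation). The log2 fold change was -3.78 ± 0.46 for Cd4, the helper T-cell coreceptor, -3.38 ± 0.46 for the receptor constant region Trbc2 and -3.76 ± 0.57 for the kinase Lck. B-cell and plasma-cell markers had a median of -2.34, with 11 of 13 lower both over all genes and adjusted over the list alone (adjusted p = 3.86e-11; adjusted p = 0.323 with an estimated correlation). The complement receptor Cr2 of B cells and follicular dendritic cells was among them (-3.59 ± 0.50). In macrophage and neutrophil markers 2 of 17 fell, Ctss (-1.28 ± 0.20) and Ptprc (-1.82 ± 0.31), and 3 adjusted over the list alone (median -0.43, adjusted p = 0.00143; adjusted p = 0.525 with an estimated correlation). The call of this list was lost without WT replicate 3 (adjusted p = 0.0718, median -0.24). Since 15 of the 17 members did not pass, the counts do not show a fall of these cells separate from the lymphocyte markers.

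NF-kB and acute-phase genes had a median of -0.74 in Snd1_KI, with 5 of 10 lower and 7 adjusted over the list alone (adjusted p = 0.000198; adjusted p = 0.232 with an estimated correlation); the vascular adhesion molecule Vcam1 fell by 1.98 ± 0.28. Vcam1 kept its call in all 9 fits that left out 1 library, while some other calls of the NF-kB list were lost without single libraries. Among interferon-stimulated genes 1 of 18 fell, Psmb8 of the immunoproteasome (-1.35 ± 0.25), and 3 adjusted over the list alone. The median of that list was -0.34 (adjusted p = 0.0205, 0.139 without WT replicate 3; adjusted p = 0.525 with an estimated correlation). Endothelial markers had 2 of 16 lower, Pecam1 (-0.69 ± 0.13) and Cldn5 (-2.06 ± 0.44, adjusted p up to 0.0632 without WT replicate 3 or Snd1_KI replicate 2 or 3), and 3 adjusted over the list alone (median -0.32, adjusted p = 0.00323; adjusted p = 0.604 with an estimated correlation). Immediate-early genes had 2 of 14 lower, Zfp36 and Klf2, and 3 adjusted over the list alone (median -0.34, adjusted p = 0.0466; adjusted p = 0.525 with an estimated correlation). This last call was lost without WT replicate 2, Snd1_KI replicate 1 or 3, or S6k2_RK replicate 1 (highest adjusted p = 0.128). Its median was -0.16 and -0.18 without Snd1_KI replicates 1 and 3 and -0.21 without WT replicate 3. The Zfp36 and Klf2 calls were lost without WT replicate 1 or 2 or any Snd1_KI library, and Klf2 also without WT replicate 3 (highest adjusted p = 0.131 and 0.123). T-cell and B-cell markers moved in the same direction as each of these lists: their mean log2 level was 6.16 ± 0.68 in WT and 3.36 ± 0.39 in Snd1_KI (SD, n = 3).

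Digestive enzymes were higher in Snd1_KI, with a median of 0.38: 4 of 35 rose and none fell, and 7 rose adjusted over the list alone (adjusted p = 4.39e-08; adjusted p = 0.525 with an estimated correlation). Besides the 2 amylase copies, the lipase-related Pnliprp2 rose from 55884 ± 6878 to 93776 ± 4191 normalized counts (0.75 ± 0.15, adjusted p = 0.00472). The phospholipase Pla2g1b rose by 0.50 ± 0.13, a call lost without WT replicate 1 or 2 or any Snd1_KI library (highest adjusted p = 0.11). In acinar transcription factors and secretory regulators 4 of 11 rose and 1 fell, with 7 and 1 adjusted over the list alone (median 0.39, adjusted p = 0.00289; adjusted p = 0.232 with an estimated correlation). Nr5a2, a nuclear receptor that maintains acinar identity, rose by 0.69 ± 0.11. Chaperones and other genes of the endoplasmic reticulum (ER) had 3 of 30 higher and 9 adjusted over the list alone (median 0.23, adjusted p = 0.000384; adjusted p = 0.525 with an estimated correlation). Genes of the ATF4 amino-acid response had 5 of 24 higher, among them Asns, Chac1 and Slc3a2, and 7 adjusted over the list alone (median 0.26, adjusted p = 0.00102; adjusted p = 0.525 with an estimated correlation). Ductal markers had 2 of 17 higher, the mucin Muc1 (0.72 ± 0.10) and the keratin Krt19 (0.56 ± 0.13), and 3 adjusted over the list alone (median 0.23, adjusted p = 0.0307; adjusted p = 0.525 with an estimated correlation; 0.0882 for the first without WT replicate 3). Single libraries decided the calls of Asns (any WT or Snd1_KI library, highest adjusted p = 0.118), Slc3a2 (WT replicate 1 or 2 or any Snd1_KI library, 0.142), Chac1 (WT replicate 1 or 3 or Snd1_KI replicate 2, 0.126) and Krt19 (WT replicate 1 or Snd1_KI replicate 2 or 3, 0.0854). They also decided calls of the ER and acinar regulator lists, among them Derl3, Pdia6 and Aqp12 (highest adjusted p = 0.141, 0.213 and 0.0939). Nr5a2 kept its call in all 9 fits that left out 1 library. With every library at the same total the medians of the ER, ATF4 and ductal lists turned to -0.057, -0.026 and -0.052. Those of enzymes and acinar regulators shrank to 0.10 (3 higher and 1 lower) and 0.11 (1 higher and 2 lower).

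Cytosolic ribosomal proteins lay slightly lower in Snd1_KI, with a median of -0.11: 5 of 77 fell, among them Rpl5 and Rps7, and 7 adjusted over the list alone (adjusted p = 0.00323; adjusted p = 0.775 with an estimated correlation). That call was lost without WT replicate 2 or Snd1_KI replicate 3 (adjusted p = 0.251 and 0.157), with medians of -0.029 and -0.063. The median was -0.17 without Snd1_KI replicate 2 and -0.19 without WT replicate 3. Mitochondrially encoded transcripts had a median of -0.36, with 1 of 12 lower, mt-Atp8, and 4 adjusted over the list alone (adjusted p = 0.00323; adjusted p = 0.604 with an estimated correlation). The calls of Rpl5, Rps7 and mt-Atp8 were each lost without WT replicate 1 or 2 or any Snd1_KI library (highest adjusted p = 0.187, 0.207 and 0.22).

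The number of genes called in Snd1_KI depended on single libraries: it was 420 without WT replicate 1, 222 without WT replicate 2, and 407, 293 and 281 without Snd1_KI replicates 1, 2 and 3. With each pair of WT libraries left out, limma called 82 genes without replicates 1 and 2, 451 without 1 and 3, and 15 without 2 and 3. With the mean level of T-cell and B-cell markers as a covariate it called 0, with 349 genes at an unadjusted p under 0.05; these settings were chosen after the data were seen. The covariate goes with the groups and raised the median SE 2.98 times, so the lost calls do not show that the changes went. List medians in that fit were 0.26 for enzymes, 0.25 for the ER list, 0.50 for the ATF4 list and -0.43 for endothelial markers, but -0.10 for NF-kB and acute-phase genes and -0.15 for ductal markers.

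**Figure D2:**
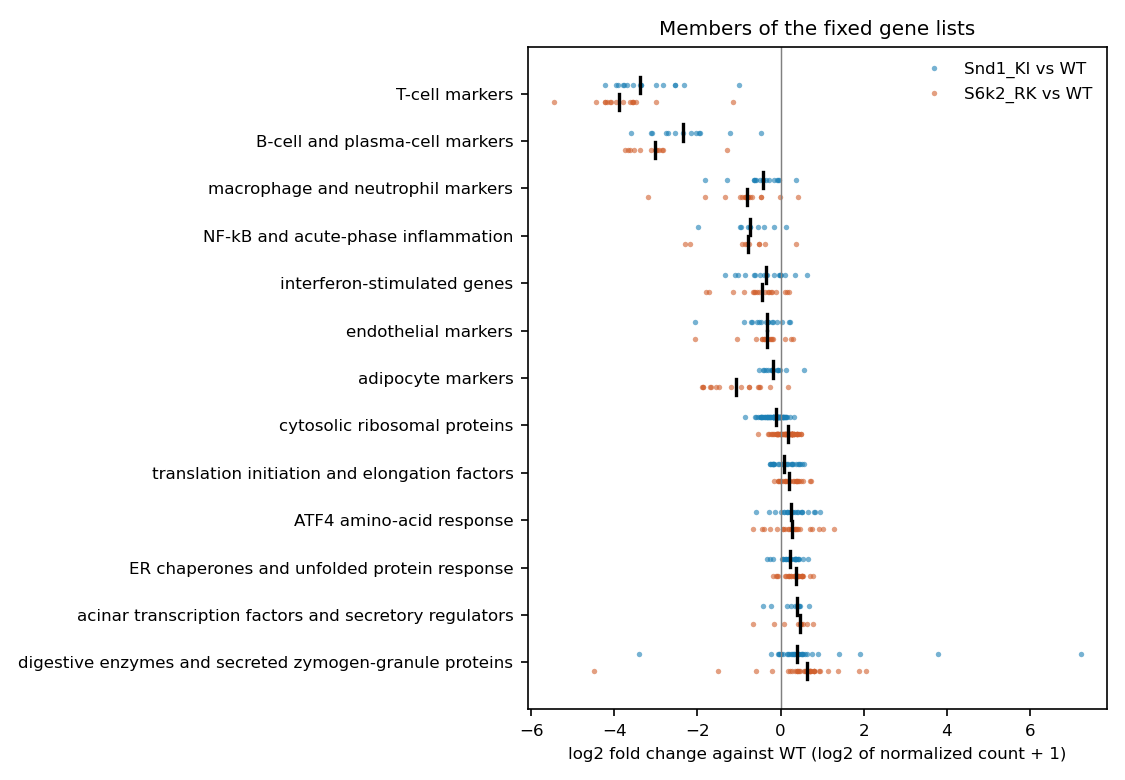
Log2 fold change against WT (x axis) of each tested member of 13 fixed gene lists (y axis), for Snd1_KI and S6k2_RK. Points are genes and black bars are list medians. The T-cell medians are -3.37 and -3.88 and the enzyme medians 0.38 and 0.63.

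The S6k2 mutant was compared with WT to ask the same question of the kinase allele. All 16 T-cell and all 13 B-cell and plasma-cell markers were lower, and 9 of 16 adipocyte markers were lower as well, while Nupr1, Mt1, Mt2, 15 of 35 digestive enzymes, 11 of 30 ER genes and 9 of 26 translation factors were higher under the authors' scaling. Marco fell from 411 ± 221 to 8.34 ± 3.58 normalized counts (log2 fold change -5.41 ± 0.35 SE, adjusted p = 7.9e-08), and Coro1a, an actin regulator of blood cells, from 418 ± 112 to 45.2 ± 13.5 (-3.18 ± 0.23, adjusted p = 1.8e-07). Glycam1 had no reads in the 3 S6k2_RK libraries and was at least 144-fold lower, against a floor of 3 reads over the group. Nupr1, a stress-induced chromatin regulator of acinar cells, rose from 9492 ± 256 to 23254 ± 2469 (1.29 ± 0.14, adjusted p = 2.87e-05). Mt2 rose from 3205 ± 776 to 9425 ± 889 (1.58 ± 0.15) and Mt1 from 4671 ± 995 to 11913 ± 1516 (1.37 ± 0.14).

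In S6k2_RK 621 genes were higher and 816 lower than in WT, against 37 and 5954 with every library at the same total and 595 and 446 at a minimum mean of 50. Of the lower genes 493 differed by more than 2-fold, and of the higher ones 40, and 3385 genes (28.3%) had groups that did not overlap, where chance gives 10%. Other falls among the 10 with the largest change by the naming rule were those of Ighg1, Cd209b, Igha, Ikzf1, Ptprc and Ltb, from -4.87 to -3.16. The other rises by that rule were the trypsinogen genes Prss1 (1.89 ± 0.55), Prss3l (1.77 ± 0.27) and Try5 (1.14 ± 0.22), H1f2 (1.49 ± 0.19), the receptor kinase Tyro3 (1.19 ± 0.20), Thsd4 (1.18 ± 0.22) and the threonine dehydrogenase Tdh (1.18 ± 0.21). Trypsinogen genes share reads with near-identical copies, so the division of their counts is uncertain, and the Prss1 call was lost without WT replicate 1 or S6k2_RK replicate 1 or 3 (highest adjusted p = 0.125), where its log2 fold change fell to 0.80 without WT replicate 1.

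For S6k2_RK against WT 14 of the 35 lists passed the threshold. All 16 T-cell markers fell, over all genes and adjusted over the list alone (median -3.88, adjusted p = 6.07e-17; adjusted p = 0.263 with an estimated correlation). The T-cell receptor segment Trac had no reads in S6k2_RK and was at least 40.8-fold lower; with it set to that bound the median was again -3.88. All 13 B-cell and plasma-cell markers fell on both counts, among them Cd79a (-3.12 ± 0.37), with a median of -3.03 (adjusted p = 1.91e-12; adjusted p = 0.27 with an estimated correlation). In macrophage and neutrophil markers 8 of 17 fell and 13 adjusted over the list alone (median -0.80, adjusted p = 9.27e-07; adjusted p = 0.374 with an estimated correlation). Among them were the lysozyme Lyz2 (-1.34 ± 0.20) and the complement gene C1qa (-0.92 ± 0.17). NF-kB and acute-phase genes had 6 of 10 lower and 7 adjusted over the list alone (median -0.79, adjusted p = 0.000223; adjusted p = 0.263 with an estimated correlation), with Vcam1 at -2.19 ± 0.28 and haptoglobin, Hp, at -2.30 ± 0.46. Interferon-stimulated genes had 4 of 18 lower and 5 adjusted over the list alone (median -0.44, adjusted p = 0.000968; adjusted p = 0.276 with an estimated correlation). Endothelial markers had 4 of 16 lower on both counts (median -0.33, adjusted p = 0.0212; adjusted p = 0.831 with an estimated correlation), a call lost without WT replicate 1 or 3 or S6k2_RK replicate 2 (highest adjusted p = 0.36), with a median of -0.088 without the last. The mean log2 level of T-cell and B-cell markers was 2.70 ± 0.41 in S6k2_RK (SD, n = 3), against 6.16 ± 0.68 in WT, so it moved with each of these lists.

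Adipocyte markers fell in S6k2_RK, 9 of 16 over all genes and 13 adjusted over the list alone (median -1.07, or -0.66 without S6k2_RK replicate 3, adjusted p = 0.000223; adjusted p = 0.679 with an estimated correlation). The adipokine Adipoq went from 239 ± 76.2 to 88.6 ± 61.4 normalized counts (-1.67 ± 0.41, adjusted p = 0.0118, 0.0508 without WT replicate 3). The complement factor Cfd (-1.56 ± 0.39) and the hormone Lep (-1.87 ± 0.49) fell too. Both calls were lost without WT replicate 3 or S6k2_RK replicate 3, and Lep also without WT replicate 1 (highest adjusted p = 0.0895 and 0.0985). Without S6k2_RK replicate 3 the log2 fold change was -0.99 for Adipoq and -1.01 for Cfd.

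Digestive enzymes had a median of 0.63 in S6k2_RK, with 15 of 35 higher and 1 lower, and 25 and 1 adjusted over the list alone (adjusted p = 1.03e-12; adjusted p = 0.276 with an estimated correlation). Pla2g1b rose from 14420 ± 415 to 27687 ± 5227 normalized counts (0.92 ± 0.13), Pnliprp2 to 107090 ± 12643 (0.94 ± 0.15) and the granule protein Sycn by 0.80 ± 0.14, while the elastase Cela3a fell by 0.60 ± 0.16. In acinar transcription factors and secretory regulators 7 of 11 rose and 1 fell, with 8 and 1 adjusted over the list alone (median 0.47, adjusted p = 0.00163; adjusted p = 0.263 with an estimated correlation). Ptf1a rose by 0.77 ± 0.16 and the water channel Aqp12 by 0.65 ± 0.10, and Rbpjl, a partner of Ptf1a in acinar cells, fell by 0.67 ± 0.12. ER chaperones and unfolded-protein-response genes had 11 of 30 higher and 18 adjusted over the list alone (median 0.37, adjusted p = 3.28e-06; adjusted p = 0.409 with an estimated correlation), among them Derl3 (0.79 ± 0.13), Xbp1 (0.54 ± 0.10) and Pdia6 (0.52 ± 0.12). The ATF4 list had 5 of 24 higher, and 9 higher and 1 lower adjusted over the list alone (median 0.28, adjusted p = 0.00712; adjusted p = 0.679 with an estimated correlation), a call lost without WT replicate 3 or S6k2_RK replicate 2 (highest adjusted p = 0.249), with a median of 0.17 without the last.

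Translation factors had 9 of 26 higher on both counts (median 0.21, adjusted p = 0.000347; adjusted p = 0.276 with an estimated correlation), including the elongation factor Eef2 (0.71 ± 0.12), Eif4b, a substrate of S6 kinases (0.53 ± 0.09), and Pdcd4, an inhibitor of initiation and also a substrate (0.73 ± 0.10). Ribosomal proteins had 12 of 77 higher on both counts, among them Rpl4 and Rpl10 (median 0.18, adjusted p = 0.000257; adjusted p = 0.831 with an estimated correlation; 0.1 for the first without WT replicate 3, with a median of 0.12). Nuclear genes of oxidative phosphorylation had 1 of 30 higher, Atp5f1a, and 1 lower, Ndufb8, on both counts (median 0.18, adjusted p = 0.0143; adjusted p = 0.831 with an estimated correlation). This call was lost without WT replicate 1 or 3 or S6k2_RK replicate 3 (highest adjusted p = 0.17). The Atp5f1a and Ndufb8 calls were lost without WT replicate 1 or 2 or S6k2_RK replicate 2 or 3, and Atp5f1a also without Snd1_KI replicate 1 (highest adjusted p = 0.118 and 0.139). The log2 fold change of Ndufb8 was -0.71, or -0.46 without S6k2_RK replicate 2. Ductal markers did not pass as a list (adjusted p = 0.324), although Muc1 rose by 0.80 ± 0.10. With every library at the same total the enzyme median shrank to 0.11 (6 higher and 3 lower). Among the lists that passed in S6k2_RK against WT, 6 medians changed sign. They became -0.046 for acinar regulators, -0.15 for the ER list, -0.24 for the ATF4 list, -0.31 for translation factors and -0.34 for ribosomal proteins and for oxidative phosphorylation.

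The count of genes called in S6k2_RK was 893 without WT replicate 1, 835 without WT replicate 2 and 748 without S6k2_RK replicate 3. It was 313 without WT replicates 1 and 2, 614 without 1 and 3 and 58 without 2 and 3, and with the lymphocyte covariate 0, with 367 genes at an unadjusted p under 0.05 (limma, these settings chosen after the data were seen). The covariate raised the median SE 3.61 times. List medians with it were 0.49 for enzymes, 0.32 for the ER list and -1.16 for adipocyte markers, but 0.14 for acinar regulators and -0.11 for NF-kB and acute-phase genes.

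Comparing the 2 mutants directly asks where they differ. The difference does not use the WT means, but the WT libraries enter the estimate of the spread. Only 14 of 11953 genes passed the threshold, 7 higher and 7 lower in S6k2_RK than in Snd1_KI, with 1207 at an unadjusted p under 0.05. The largest of the 7 rises was that of 1810009J06Rik, a protein-coding gene that the naming rule leaves out by its symbol. It stood at 105 ± 5.67 normalized counts in Snd1_KI and 539 ± 229 in S6k2_RK (log2 difference 2.26 ± 0.30 SE, limma adjusted p = 0.00261). Nupr1 stood at 12211 ± 2632 normalized counts in Snd1_KI and 23254 ± 2469 in S6k2_RK (log2 difference 0.95 ± 0.14 SE, limma adjusted p = 0.00482). The trypsin inhibitor Spink1 stood at 4017 ± 435 and 6995 ± 1489 (0.79 ± 0.13, adjusted p = 0.0128). The growth-related Tpt1 stood at 16472 ± 288 and 25044 ± 2128 (0.60 ± 0.11), the mitochondrial leucyl-tRNA synthetase Lars2 at 7345 ± 711 and 15129 ± 4951 (0.99 ± 0.18), and Cibar1 at 61.0 ± 6.59 and 112 ± 3.91 (0.88 ± 0.17). The RNA gene Gm42418, chosen after its values were seen, moved with Lars2: the S6k2_RK replicates 1, 2 and 3 had 65900, 116180 and 146640 normalized counts of it and 9654, 16438 and 19294 of Lars2. Gm42418 averaged 50285 ± 5206 in WT, 59289 ± 6829 in Snd1_KI and 109570 ± 40773 in S6k2_RK, and its difference between the mutants did not pass (0.82 ± 0.21, adjusted p = 0.169). Why Lars2 and Gm42418 moved together was not tested, so the Lars2 difference is not shown to be one of the synthetase gene itself. Lower in S6k2_RK were Serpina10, an inhibitor of coagulation proteases (234 ± 62.0 against 84.8 ± 13.2), BC034090 (322 ± 34.0 against 148 ± 20.9), Klk1b11 (251 ± 11.1 against 125 ± 16.2) and Cela3a (433 ± 96.7 against 218 ± 39.6). Amy2a4 had 1218 reads in Snd1_KI and 15 in S6k2_RK, a ratio of 61.3 after scaling (95% interval 37.0 to 110, counting error only).

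Between the mutants 12 of 35 lists passed with the preset correlation. All 77 ribosomal proteins had a higher fitted value in S6k2_RK (median 0.30, adjusted p = 8.37e-22; adjusted p = 0.707 with an estimated correlation); none passed over all genes and 41 did adjusted over the list alone. With every library at the same total this median shrank to 0.060 and that of digestive enzymes to 0.021. The share of counts in ribosomal proteins was 1.57% ± 0.121 in Snd1_KI and 1.64% ± 0.258 in S6k2_RK (mean ± SD, n = 3), with libraries that overlapped. In WT it was 2.19% ± 0.294. The mean share of S6k2_RK thus lay below that of WT, although the list median against WT was 0.18 under the authors' scaling. Translation factors (median 0.14, 1 of 26 higher and 5 adjusted over the list alone), oxidative phosphorylation (0.18, 0 of 30 on both counts), ER chaperones (0.13, 0 of 30 on both counts) and mitochondrially encoded transcripts (0.18, 0 of 12 on both counts) also lay higher, with adjusted p = 0.00165, 7.76e-05, 0.0194 and 0.0346; with an estimated correlation adjusted p = 0.707, 0.707, 0.887 and 0.887. Digestive enzymes had a median of 0.26 but a mean of -0.13, with 1 of 35 higher and 2 lower and 8 and 4 adjusted over the list alone (adjusted p = 8.3e-06; adjusted p = 0.707 with an estimated correlation). Adipocyte markers lay lower in S6k2_RK, with 0 of 16 past the threshold over all genes and 9 adjusted over the list alone (median -1.24, adjusted p = 2.26e-05; adjusted p = 0.707 with an estimated correlation). Macrophage and neutrophil markers (-0.37, 0 of 17, 5 adjusted over the list alone), B-cell markers (-0.91, 0 of 13 on both counts) and T-cell markers (-0.40, 0 of 16, 1 adjusted over the list alone) lay lower too. Their adjusted p were 0.000191, 0.00113 and 0.0227, and with an estimated correlation adjusted p = 0.707, 0.721 and 0.887. Schwann-cell and mesothelial markers (-0.78, 0 of 7, 4 adjusted over the list alone) and clock genes (-0.21, 0 of 15 on both counts) lay lower with adjusted p = 0.0194 each, and adjusted p = 0.707 each with an estimated correlation. With every library at the same total the medians of translation factors, oxidative phosphorylation, ER chaperones and mitochondrially encoded transcripts turned negative. Single libraries decided the calls of the B-cell and clock lists (S6k2_RK replicate 3, adjusted p = 0.276 and 0.336), the T-cell list (S6k2_RK replicate 2 or Snd1_KI replicate 1, up to 0.609) and the Schwann-cell list (S6k2_RK replicate 3 or Snd1_KI replicate 1 or 3, up to 0.159). They also decided those of the ER list (S6k2_RK replicate 2 or 3 or Snd1_KI replicate 2, up to 0.428) and the mitochondrially encoded list (S6k2_RK replicate 1 or 3 or Snd1_KI replicate 1, up to 0.515). Without S6k2_RK replicate 3, 7 lists passed, and the medians were -0.59 for adipocyte, -0.32 for B-cell, -0.19 for macrophage and neutrophil and -0.49 for Schwann-cell and mesothelial markers, -0.14 for clock genes, 0.16 for digestive enzymes, 0.12 for oxidative phosphorylation and 0.084 for mitochondrially encoded transcripts. Without S6k2_RK replicate 1 the clock median was -0.38 and the mitochondrially encoded median 0.022. Without S6k2_RK replicate 2 the ER median was 0.051, the T-cell median -0.20 and the mitochondrially encoded median 0.39. Without Snd1_KI replicate 1 the T-cell median was -0.0052 and the mitochondrially encoded median 0.090, and without Snd1_KI replicate 3 the T-cell median was -0.64.

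The calls between the mutants rested on single libraries. There were 85 without S6k2_RK replicate 1, 35 without S6k2_RK replicate 2, 6 without S6k2_RK replicate 3, 22 without WT replicate 2, and 8, 4 and 7 without Snd1_KI replicates 1, 2 and 3. Of the 10 named genes, Nupr1 and BC034090 kept their call in all 9 fits that left out 1 library. Lars2 and Cibar1 lost it without WT replicate 1, any Snd1_KI library or S6k2_RK replicate 2 or 3 (highest adjusted p = 0.187 and 0.236), and Tpt1 without WT replicate 1, any Snd1_KI library or S6k2_RK replicate 3 (0.195). Amy2a4 lost it without Snd1_KI replicate 1 or 3 or S6k2_RK replicate 3 (0.141), Cela3a without Snd1_KI replicate 1 or 2 or S6k2_RK replicate 3 (0.157), and Spink1 without Snd1_KI replicate 2 or S6k2_RK replicate 3 (0.139). Klk1b11 lost it without Snd1_KI replicate 1 or 2 (0.0844) and Serpina10 without Snd1_KI replicate 2 (0.0545).

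The mean of both mutants was set against WT because the title names 1 interaction that both alleles concern. This contrast had 675 genes higher and 780 lower, against 53 and 4909 with every library at the same total and 648 and 433 at a minimum mean of 50. The largest rises by the naming rule were H1f2 (1.36 ± 0.16), Mt2 (1.36 ± 0.13), Mt1 (1.18 ± 0.12), Thsd4 (1.09 ± 0.19) and Fam81a (1.04 ± 0.17), and falls named by it were those of Glycam1, Ighg1, Marco and Cd209b, from -6.84 to -3.65. Of the 35 lists 13 passed, 5 higher and 8 lower, led by T-cell markers (median -3.65, 16 of 16 lower on both counts) and, among the higher ones, digestive enzymes (median 0.49, 14 of 35 higher and 25 adjusted over the list alone). Their adjusted p were 3.08e-18 and 3.56e-12, and with an estimated correlation adjusted p = 0.194 and 0.373. The count of genes was 862 without WT replicate 1 and 675 without WT replicate 2. It was 210 without WT replicates 1 and 2, 638 without 1 and 3 and 20 without 2 and 3, and with the lymphocyte covariate 0, with 350 genes at an unadjusted p under 0.05 and a median SE 3.76 times as large.

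The 2 mutants shared 206 of the higher calls, where independent lists would share 14.9, and 322 of the lower calls, where independent lists would share 26.1. No gene was called in opposite directions. Across the 11953 genes, which are not independent replicates, the log2 fold changes against WT had a Pearson r of 0.812 and a Spearman rho of 0.709. Draws of 9 unchanged libraries, with 1 simulated WT group shared by both comparisons, gave 0.499 and 0.465 on average, and 0.06 shared calls. Genes were drawn independently in them. The draws therefore hold no WT difference common to many genes, such as that of lymphocyte transcripts, and give no chance level for it. The covariance was 0.246 against a simulated 0.0348, a difference of 0.211. The 3 WT libraries cannot be split into separate groups of 2, so part of the excess may come from the shared controls.

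**Figure D3:**
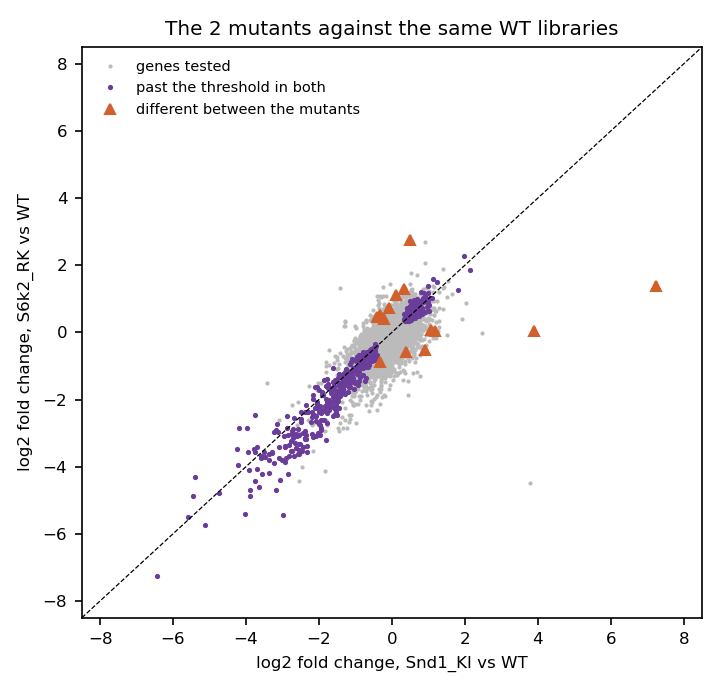
Log2 fold change of each tested gene in Snd1_KI against WT (x axis) and in S6k2_RK against WT (y axis), with the line of equal change dashed. Purple points are the 528 genes called in both, and triangles the 14 genes that differ between the mutants, with Amy2a4 at 7.23 on the x axis.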

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

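The tests on scaling and on a lower share of other cell types were chosen after the result was seen. The lymph-node genes were listed after 4 of the 14 had been seen, and the test uses the 10 that had not.

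The effects of the 2 mutations against WT were compared by limma's test of their difference, which for these groups is the difference of S6k2_RK and Snd1_KI. Groups of 3 were not tested for single libraries far from the others. The log2 difference was 0.99 for Lars2, 0.95 for Nupr1, 0.88 for Cibar1, 0.79 for Spink1 and 0.60 for Tpt1. It was -5.85 for Amy2a4, -1.43 for Serpina10, -1.13 for BC034090, -1.01 for Klk1b11 and -0.98 for Cela3a. Serpina10, BC034090 and Klk1b11 lay above WT in Snd1_KI, and Nupr1, Spink1 and Lars2 lay above WT in S6k2_RK.

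Splits of the libraries into other groups were counted for each comparison. Snd1_KI against WT gave 670 genes, S6k2_RK against WT 1437 and S6k2_RK against Snd1_KI 14, where the highest other split gave 0, 0 and 1. Only the real split, 1 of the 10, gave as many genes in each case, and 10 splits are too few for a share under 0.05. For the mean of both mutants against WT, only the real split, 1 of 84, gave as many genes (1455). Most of the other splits mixed genotypes within a fitted group, which raises the spread and removes calls. This share therefore does not exclude chance. The split that set the 3 Snd1_KI libraries against the rest kept each genotype together and gave 8 genes. The highest other split, with 518 genes, set the 3 S6k2_RK libraries against the rest, and the next, with 347, held 2 of these 3 libraries.

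The first pattern is the lower level of lymphocyte transcripts in both mutants. Scaling was argued against: the T-cell median was -3.37 or lower in both mutants under each of 4 scalings. Lymph-node tissue carried along with the WT pancreas may contribute, since 10 of 10 listed lymph-node genes that had not been seen were lower in both mutants, with a median log2 fold change of -2.17 in Snd1_KI and -2.43 in S6k2_RK. The most abundant of these were Ccl21a (263 ± 110 normalized counts in WT, 55.2 ± 12.3 in Snd1_KI and 75.8 ± 47.9 in S6k2_RK), Lyve1 (154 ± 35.2, 92.8 ± 7.52 and 58.1 ± 6.35), Cxcl13 (131 ± 22.5, 104 ± 9.0 and 73.3 ± 95.1) and Siglec1 (128 ± 48.0, 26.7 ± 7.70 and 24.1 ± 9.36), and 1 of the 14 genes, Cr2, is also in a fixed list. Of the 10, Chst4, Fut7 and Ubd had means below 10 normalized counts (4.90, 3.37 and 1.90), and Fcer2a is also a gene of B cells. A biological difference in lymphocytes between the genotypes stays open and untested, since ground tissue does not separate lymphocytes within the pancreas from those of a lymph node.

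The second pattern is the higher level of digestive-enzyme transcripts relative to other genes. A transcript length or GC trend was argued against, since the list median after that correction was 0.46 in Snd1_KI and 0.62 in S6k2_RK. A lower share of all other pancreatic cell types stays open. Ductal and islet markers moved apart, with a mean log2 fold change of 0.22 and -0.24 in Snd1_KI (two-sided permutation p = 1e-05, the smallest the permutations can give) and 0.10 and -0.14 in S6k2_RK (permutation p = 0.0482, close to the threshold). The permutations shuffled genes, so these p do not measure the spread between mice. At equal totals the ductal median of Snd1_KI turned negative, so a fall of both marker sets is not excluded. Without single libraries the S6k2_RK list medians ranged from 1e-04 to 0.17 for ductal markers. They ranged from -0.16 to 0.093 for beta-cell and from -0.40 to 0.11 for other islet markers, which together made up the islet markers tested. The authors' scaling was argued against for this relative rise: no factor per library can change a share of counts, and the enzyme share was higher by 3.68 percentage points in Snd1_KI and 5.11 in S6k2_RK, with every mutant library above every WT library (exact p = 0.1, the smallest possible). Whether the enzymes rose apart from the level of other genes cannot be told apart from scaling, since at equal totals the list median was 0.10 and 0.11, with 3 of 3 Snd1_KI but 0 of 3 S6k2_RK libraries above every WT library by list mean, and an effect of the mutations on enzyme genes stays open and untested.

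The third pattern is the set of genes that differ between the mutants. Variants carried along around the edited loci stay open: 1 of 14 genes (7.14%) lay within 20 Mb of Snd1 or Rps6kb2, against 3.15% of the other genes (Fisher exact p = 0.362), and 14 genes are too few to decide. That gene, 1810009J06Rik near Snd1, rose in S6k2_RK (log2 fold change 2.75, limma adjusted p = 2.92e-05), whose label names no edit at Snd1. In Snd1_KI against WT it did not pass (0.49, limma adjusted p = 0.376). Near Rps6kb2 the share was raised among the calls of both mutants against WT, 3.20% against 1.72% in S6k2_RK (Fisher exact p = 0.000399) and 3.88% against 1.78% in Snd1_KI, whose label names no edit there (0.000609), while near Snd1 it was 1.19% against 1.26% in Snd1_KI (Fisher exact p = 1) and 1.95% against 1.16% in S6k2_RK (0.016). These tests take genes as independent, although neighbouring genes may move together, so the raised shares do not decide for carried variants. For Amy2a4, reads shared between amylase copies stay open. The summed Amy2a copies also differed, by -1.76 on the log2 scale, which a division of reads among these copies does not give. But Amy2a4 held only 858, 37.9 and 190 of the 19881, 70820 and 70632 normalized counts of the sum in Snd1_KI replicates 1, 2 and 3. The sum therefore does not show how its own reads were assigned, and single copies were erratic between libraries. An effect of the alleles stays open and untested for all of these genes.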

How the results depend on the processing

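The lymphocyte covariate, the length and GC correction, the pairs of WT libraries, the tests without the first S6k2_RK library and the list medians under other scalings were chosen after the data were seen.

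Counts of genes stayed within 1.5 times the reported ones under pseudocounts of 0.5 and 10, a minimum mean of 1 or none, TMM, rescaling to genes outside the enzyme and mitochondrial lists, the replicate block, only the groups compared, and edgeR with all 9 libraries. The replicate numbers do not pair the libraries (correlations of same-numbered pairs -0.08 to 0.05).

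A minimum mean of 50, with 8097 genes tested, turned the balance of calls. For Snd1_KI against WT it gave 409 genes, 243 higher and 166 lower (287 and 383 as reported), for S6k2_RK 595 and 446 (621 and 816) and for the mean of both mutants 648 and 433 (675 and 780). For Snd1_KI array weights gave 1128. Scaling to equal totals gave 1626, 45 higher and 1581 lower, as the median gene shifted by -0.28. Leaving out pairs of WT libraries gave 82, 451 and 15 genes, and single libraries 222 to 824. For S6k2_RK against WT equal totals gave 5991 genes, 37 higher and 5954 lower, the pairs 313, 614 and 58, and single libraries 748 to 1864. For the mean of both mutants equal totals gave 4962, 53 higher and 4909 lower, the pairs 210, 638 and 20, and single libraries 675 to 1848. With 1 WT library left, that library is assumed to vary like the other groups.

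Between the mutants equal totals gave 35 genes, 4 higher and 31 lower, the robust fit 23 (14 and 9), array weights 40 (20 and 20), the length and GC correction 9 (3 and 6) and DESeq2 53 (49 and 4, with 1293 genes given an adjusted p). Without the first S6k2_RK library edgeR gave 70 and DESeq2 93, and leaving out single libraries gave 4 to 85. The cause was not tested.

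The lymphocyte covariate left 0 genes in each of the 4 comparisons (limma), with 349, 367, 858 and 350 at an unadjusted p under 0.05, where chance gives 598. It is confounded with the groups and raised the median SE by 2.98, 3.61, 1.22 and 3.76 times, so the loss does not show what the covariate explains. Lists past the threshold were then 6, 6, 6 and 5. With an estimated correlation 0 lists passed in each (4, 5, 0 and 4 at an unadjusted p under 0.05), and fry gave 4, 9, 0 and 10. Leaving out single libraries gave 12 to 18, 11 to 15, 7 to 17 and 12 to 16 lists.

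Equal totals reversed medians of lists past the threshold, and other lists are not given here. In Snd1_KI they became -0.057 for ER chaperones, -0.026 for the ATF4 list and -0.052 for ductal markers. In S6k2_RK they became -0.046 for acinar regulators, -0.15 for ER chaperones, -0.24 for the ATF4 list, -0.34 for ribosomal proteins, -0.31 for translation factors and -0.34 for oxidative phosphorylation. Between the mutants they became -0.11 for ER chaperones, -0.10 for translation factors, -0.054 for oxidative phosphorylation and -0.055 for mitochondrially encoded transcripts (-0.038 under the length and GC correction). For the mean of both they became -0.10 for ER chaperones, -0.14 for the ATF4 list and -0.27 for translation factors. The shift of all genes accounts for the size of those under equal totals. The log2 fold change of mt-Nd1 in S6k2_RK ranged from -0.35 to 0.029 without single libraries, the latter without S6k2_RK replicate 2.

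The correlation between the mutants was 0.757 with a minimum mean of 50 and 0.779 to 0.839 without single libraries. Without near-identical copies the enzyme share differed by 2.93 points in Snd1_KI, 3.44 in S6k2_RK and 0.504 between the mutants (exact p = 0.1, 0.1 and 0.5), and without single libraries by 3.32 to 4.14, 4.75 to 5.62 and 1.13 to 1.94. Covariates for sex were not run, since all 9 libraries held Y-linked transcripts.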

Other observations

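Some fixed lists did not pass the threshold in either mutant and had single members called by limma. These members were chosen after their values were seen. In the mTOR and S6K pathway list 5 of 31 genes rose in Snd1_KI and 7 rose and 1 fell in S6k2_RK (camera adjusted p = 0.0953 and 0.174). Deptor rose by 0.55 and 0.48, Insr by 0.58 and 0.56, and Sesn1 fell by 1.11 on the log2 scale in S6k2_RK. In the list of arginine methyltransferases and Tudor proteins Snd1 was the 1 call among 17 genes in each mutant (camera adjusted p = 0.861 and 0.864). In the acinar injury list 4 of 23 genes rose in Snd1_KI and 5 rose and 1 fell in S6k2_RK (camera adjusted p = 0.0737 and 0.374). Krt18 rose by 0.47 and 0.66, Clu by 0.60 and 0.65, and Krt20 by 1.97 and 2.28, while Anxa2 fell by 0.63 in S6k2_RK. In the fibroblast and stellate list 3 of 21 genes fell in each mutant (camera adjusted p = 0.861 and 0.496), Acta2 by 0.97 and 0.73 and Tagln by 1.08 and 0.80.

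The first principal component of the 9 libraries held 41.6% of the variance and the next 12.4%.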
